A study of Mus musculus with 16 samples.

How the data were processed

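RNA sequencing measured total RNA from bone marrow-derived macrophages of the Apoe-deficient mouse line named in the labels, in 16 libraries of 4 groups with 4 replicates each. The authors aligned the reads with STAR 2.6.1d to the mouse genome (builds mm10 and GRCm38 are both named) and deposited, for each library, the counts of uniquely mapped reads per gene that STAR writes. These deposited counts are whole numbers without any normalization, and each file gives them without regard to strand, on the strand of the gene and on the opposite strand. The annotation release is not given. Of the 54838 gene identifiers in the files, 54809 matched GENCODE M21, which gave symbols, positions and biotypes; the other 29 held at most 0.002% of a library's counts. The first 4 lines of each file name no gene and hold the unmapped, multimapped, unassigned and ambiguous reads, which were used for quality measures. A gene that shares sequence with close relatives (the Ifi200 family, Ifit3 and Ifit3b, the Oas, H2 and Bcl2a1 families) keeps only its uniquely mapped part, so its level is less certain.

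The strand column whose total was at least 5 times the other's was used, which in all libraries was the opposite strand; reads on the other strand made up 3.19% to 3.72%. Counts on genes came to 7.49 to 31.6 per library in units of 1e6. A floor of 3 counts corresponds to 0.095 to 0.401 counts per 1e6 counted reads (CPM), and floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a group differed by far more than counting error: the chi-square per gene between 2 replicates was 13.97 to 80.3 over 24 pairs.

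Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, 2-sided) after TMM normalization and the filterByExpr filter, which kept 12612 genes. All 16 libraries entered 1 model with a mean per group, and 6 contrasts were taken from it. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Changes are log2 fold changes ± SE, from 4 libraries against 4, and levels are mean CPM ± SD. The p-values measure the spread between these libraries only: the labels do not say whether replicates came from separate animals or separate cultures of 1 preparation. They also leave open whether the cells given TNFα alone received DMSO.

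Gene groups were 27 lists of 762 genes, written from textbook knowledge: inflammatory cytokines and chemokines, NF-kB pathway components and feedback genes, adhesion and matrix genes, interferon-stimulated genes, antigen presentation, cholesterol biosynthesis, lipid handling, alternative activation, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, oxidative stress (NRF2), unfolded protein and integrated stress response, apoptosis and survival, class IIa HDACs with MEF2 and immediate-early genes, other HDACs and corepressors, lysosome and phagocytosis, macrophage identity, osteoclast, neutrophil, lymphocyte, dendritic cell, mast cell, erythroid and megakaryocyte, and stromal and endothelial markers, mitochondrially encoded transcripts and ribosomal protein genes. Each list was tested against all other genes with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and adjustment over the 27 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were alternatives. With an estimated correlation the calls that held were 2 of 5 in the direct comparison of the inhibitors and 0 in each other contrast, and 0 in every contrast with the replicate block as well. Member counts are given over all genes tested and adjusted over the list alone. Lists, tests, thresholds, alternatives and the rule for named genes were fixed before the data were examined, except where stated.

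Genes are named by this rule. For the contrast of TNFα with DMSO and of each inhibitor with TNFα alone, it takes the 6 rising and 6 falling genes with the largest change among those past the threshold, with a mean of at least 5 CPM, all 4 libraries of one group above all 4 of the other, and a symbol that is not a clone or a predicted gene. From each list called by camera it takes up to 3 members with the smallest adjusted p, from any other list at most 1 past the threshold, and from lists of other cell types or quality the member with the highest level. It adds Apoe, Tnf, Nfkbia, Ikbkb, Chuk, Hdac4, Hdac5, Hdac7, Hdac9, Ccl2, Il1b, Il6 and Icam1. The direct comparison of the inhibitors adds 4 genes per direction, and the contrasts of the inhibitor groups with DMSO use genes already named. Other genes are said to be chosen after their values were seen. Some genes that the rule names are not reported here, but stay in the counts.

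Whether equal replicate numbers mark samples handled together was checked from the data: after removal of group means, the correlation between same-number libraries of 2 groups had to be at least 0.1 in every pair. It was 0.33 to 0.681 for TNFα with DMSO, 0.375 to 0.675 for TMP195+TNFα with TNFα and 0.27 to 0.645 for TMP195+TNFα with DMSO, so fits with the replicate number as a block are given beside these contrasts where they change a call, with counts for many of the lists that move. For the 3 contrasts of the TPCA-1 group the lowest pairs were at -0.043, -0.007 and 0.02, and the block is only an alternative there. Without TPCA-1+TNFα 2 the pairs of these contrasts all passed, at 0.292 to 0.487 with TNFα, 0.288 to 0.44 with TMP195+TNFα and 0.104 to 0.328 with DMSO, so calls with the block and without that library are given too.

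The alternatives were DESeq2 size factors, the DESeq2 1.42.0 test, limma voom with library weights, no filter, a filter of at least 5 CPM in at least 4 libraries, unstranded counts, only the 2 groups compared, the replicate block, a 2-fold threshold, and leaving out each library in turn. Leaving TPCA-1+TNFα 2 out of the shared fit, leaving it out together with the block, for counts, lists and named genes, and the block with an estimated correlation were added after seeing the data. Counts of changed genes were compared with those from all 35 splits of the 8 libraries of a contrast. For the relation between both inhibitors' changes, which share the TNFα libraries, 20 simulations with no inhibitor effect and the 6 assignments that split the TNFα libraries 2 and 2 were set beside the observed values, covariances included.

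The fit was also tested on simulated counts for 12612 genes with the spread of these libraries, with changes of 1.5-, 2- and 4-fold planted in 67, 67 and 66 genes. For TNFα with DMSO it recovered 26.9%, 59.7% and 95.5% of them, for TMP195+TNFα with TNFα 32.8%, 73.1% and 97%, and for TPCA-1+TNFα with TNFα 28.4%, 76.1% and 98.5%. For the direct comparison the shares were 22.4%, 59.7% and 89.4%, for TMP195+TNFα with DMSO 38.8%, 68.7% and 95.5%, and for TPCA-1+TNFα with DMSO 25.4%, 61.2% and 97%. False calls were 1.6% to 6.6% of calls. Each contrast called a planted list of 30 genes and 0 of 20 others, but correlated genes were not simulated. No deposited library was left out of the main results.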

Results

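The data are read counts per gene from bone marrow-derived macrophages of mice lacking apolipoprotein E (genotype label B6.129P2-Apoetm1Unc/J, strain label C57BL/6J). Each of the 4 groups holds 4 libraries: cells given DMSO, cells given TNFα (50 ng/ml, 24 h), and cells given an inhibitor for 1 h before the same TNFα stimulation. TMP195, used at 5 µM, inhibits class IIa histone deacetylases. TPCA-1, used at 500 nM, inhibits IKK2, the kinase encoded by Ikbkb, and is not an analog of TMP195. In order of replicate number, counted reads (in units of 1e6) were 18.9, 19.6, 21.8 and 18.8 for DMSO and 18.6, 20.3, 31.6 and 20.9 for TNFα. They were 18.6, 20.6, 18.9 and 22.9 for TMP195+TNFα and 20.99, 7.49, 20.4 and 20.5 for TPCA-1+TNFα. TPCA-1+TNFα 2 also left 44.0% of its reads unmapped, against 4.0% to 7.1% in the other 15 libraries. Apoe (ENSMUSG00000002985), the gene named in the genotype, had 1 to 11 reads per library and was too low to test. The first principal component carried 32.7% of the variance and the second 28.9%.

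**Figure D1:**
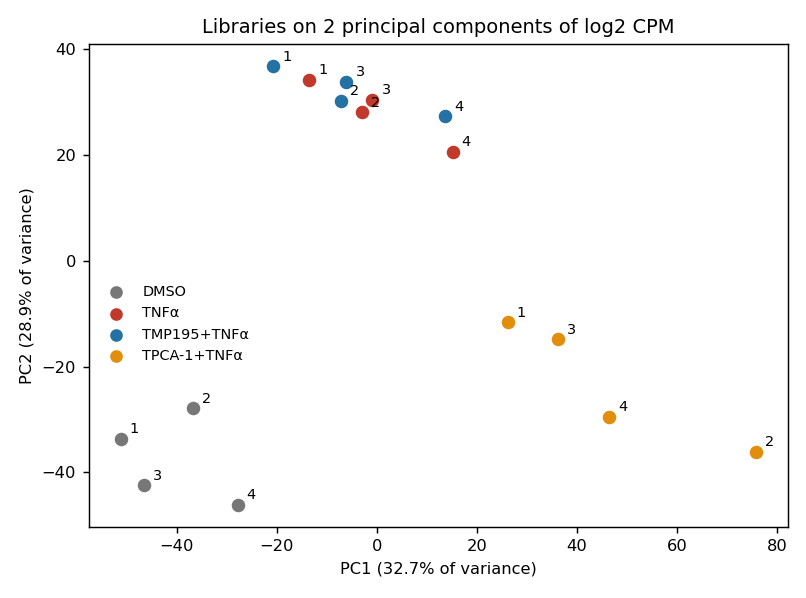
Principal components of log2 CPM; each point is 1 library, coloured by group and numbered by replicate. TPCA-1+TNFα 2 lies farthest along the first component, at 75.84, and the other libraries of its group at 26.17 to 46.53.

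The first comparison asks what TNFα did to these macrophages. After 24 h, TNFα raised 2 chemokines that attract neutrophils: Cxcl1 (ENSMUSG00000029380, GRCm38 chromosome 5, 90891241 to 90893115) went from 2.00 ± 1.45 CPM in DMSO to 102 ± 48.3 CPM (SD, n = 4), and Cxcl3 from 0.986 ± 0.703 to 146 ± 28.6 CPM. Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), which encodes cyclooxygenase-2, rose from 3.27 ± 0.845 to 116 ± 21.02 CPM. Of 40 cell cycle genes 39 fell (list adjusted p = 0.0584 with an estimated correlation). The mannose receptor Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) fell from 333 ± 104 to 27.9 ± 6.28 CPM. In all, 1377 of 12612 genes were higher and 1568 lower, 1242 of them by at least 2-fold. Rankings here and below hold within the filters for named genes (a mean of at least 5 CPM, no overlap between the 2 groups, no clone or predicted gene). The rising genes with the largest changes were then Susd2 (log2 7.92 ± 0.94, SE), Cxcl3 (7.22 ± 0.49), the alcohol dehydrogenase Adh7 (6.63 ± 0.43), the acute-phase gene Saa3 (6.61 ± 0.61), the class I-like H2-M2 (6.12 ± 0.64) and Cxcl1 (5.65 ± 0.70). The falling ones were the ribonucleotide reductase subunit Rrm2 (-3.85 ± 0.35), the G-protein regulator Rgs2 (-3.81 ± 0.36), Pclaf (-3.71 ± 0.34), Mrc1 (-3.58 ± 0.29), the sulfotransferase Sult1a1 (-3.31 ± 0.33) and Rnf150 (-3.18 ± 0.16). Adjusted p values of these 12 genes ran from 1.67e-09 to 1.08e-05.

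Of 27 tested inflammatory cytokines and chemokines 15 rose and 3 fell (17 and 4, where here and below a list's counts in parentheses are adjusted over the list alone). Camera gave this list an adjusted p = 1.81e-06, and 0.074 with an estimated correlation. Cxcl2 (5.27 ± 0.28), Ptgs2 (5.15 ± 0.28), Il6 (3.60 ± 0.55, adjusted p = 9.18e-05) and Il1b (3.45 ± 0.44, adjusted p = 1.43e-05) were among those that rose. Tnf itself (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) rose by 1.29 ± 0.16, from 243 ± 44.5 to 594 ± 95.9 CPM. The 3 that fell, named after their values were seen, were the monocyte chemoattractants Ccl7 (-2.09 ± 0.42), Ccl12 (-0.94 ± 0.33) and Ccl8 (-0.65 ± 0.22). The call of Ccl12 ended without TNFα 2, 3 or 4 or DMSO 1 or 3 (highest adjusted p = 0.143, without DMSO 3), and that of Ccl8 without TNFα 2, 3 or 4 or DMSO 1, 2 or 3 (highest adjusted p = 0.144, without DMSO 1). Their relative Ccl2 stood at -0.93 ± 0.34 (adjusted p = 0.0601), and at -0.98 ± 0.19 (adjusted p = 0.000829) with the replicate number as a block. Among 30 NF-kB pathway and feedback genes 16 rose (16), among them Traf1 (3.08 ± 0.17), the inhibitor gene Nfkbie (2.02 ± 0.21) and Birc3 (1.27 ± 0.14). The NF-kB list had a camera adjusted p = 1.28e-08, and 0.0584 with an estimated correlation. Nfkbia, another feedback inhibitor, rose by 1.61 ± 0.20 (adjusted p = 1.14e-05). The kinase genes Ikbkb (ENSMUSG00000031537, chromosome 8, 22659212 to 22706589) and Chuk stood at 0.16 ± 0.08 (adjusted p = 0.187) and 0.17 ± 0.15 (adjusted p = 0.459).

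Adjusted over the list alone, 40 of the 40 cell cycle genes fell, with a median of -2.16, among them the replication helicase genes Mcm5 (ENSMUSG00000005410, chromosome 8, 75109569 to 75128439; -2.63 ± 0.20) and Mcm2 (-2.38 ± 0.17) and the mitotic kinase Cdk1 (-1.81 ± 0.14). The cell cycle list had a camera adjusted p = 7.38e-32, and 0.0584 with an estimated correlation. NRF2 genes of the oxidative stress response rose in 22 of 30 cases (24), including the cystine transporter Slc7a11 (4.29 ± 0.26), the superoxide dismutase Sod2 (2.76 ± 0.19) and glutathione reductase Gsr (1.80 ± 0.15). The NRF2 list had a camera adjusted p = 2.09e-15, and 0.0584 with an estimated correlation. Glycolysis and hypoxia genes rose in 22 of 30 cases and fell in 1 (24 and 2), with Adm (2.91 ± 0.29), the oxygen sensor Egln3 (1.99 ± 0.24) and the glucose transporter Slc2a1 (1.32 ± 0.15) among the rising ones. This list had a camera adjusted p = 5.42e-08, and 0.134 with an estimated correlation. In the apoptosis and survival list 16 of 34 rose and 3 fell (16 and 3), with higher levels of Ier3 (2.46 ± 0.15), the death receptor Fas (2.12 ± 0.19) and its inhibitor Cflar (0.77 ± 0.09). Its camera adjusted p = 0.00175, and 0.0584 with an estimated correlation. The cholesterol list of 25 genes was not called (camera adjusted p = 0.0602). With the replicate block 8 of its members rose (camera adjusted p = 0.00223, and 0.701 with an estimated correlation).

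Camera called 3 further lists lower after TNFα. Macrophage identity genes fell in 14 of 33 cases and rose in 2 (15 and 2), with the receptor Tlr9 (-1.72 ± 0.23) and the complement subunit C1qc (-1.14 ± 0.15) among the falling ones. The macrophage identity list had a camera adjusted p = 0.00559, and 0.318 with an estimated correlation. Lysosome genes fell in 11 of 36 and rose in 2 (11 and 2), for example the proton pump subunit Atp6v0a1 (-0.71 ± 0.12) and Gusb (-0.47 ± 0.08). The lysosome list had a camera adjusted p = 0.00471, and 0.14 with an estimated correlation. Alternative-activation genes fell in 8 of 16 and rose in 3 (9 and 3). Here Mrc1 and the efferocytosis ligand Gas6 (-1.57 ± 0.17) fell and Tgm2 rose (1.22 ± 0.19). Camera's adjusted p = 0.0354 for these genes, and adjusted p = 0.318 with an estimated correlation. The call ended without TNFα 1 (adjusted p = 0.0535) or DMSO 4 (adjusted p = 0.0532).

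The deacetylase in the study's title, Hdac9 (ENSMUSG00000004698, chromosome 12, 34047580 to 34917095), fell from 12.5 ± 2.59 to 3.95 ± 0.448 CPM (-1.66 ± 0.18, adjusted p = 3.45e-06). Its class IIa relative Hdac5 fell by 0.80 ± 0.20 (adjusted p = 0.00622), while Hdac4 (-0.04 ± 0.16, adjusted p = 0.906) and Hdac7 (-0.05 ± 0.21, adjusted p = 0.902) did not pass. Their list, with 6 of 25 higher and 7 lower (6 and 8), and 6 and 10 with the block, was not called (adjusted p = 0.756). Neutrophil markers were higher in 2 of 4 (3), namely S100a8 (5.38 ± 0.40) and Lcn2 (3.81 ± 0.30), chosen after their values were seen. Camera gave neutrophil markers an adjusted p = 0.00272, and 0.0621 with an estimated correlation. Their most abundant member, the receptor Csf3r, stood at 0.58 ± 0.24 (adjusted p = 0.0879), or 0.59 ± 0.15 (adjusted p = 0.00672) with the replicate block. All 3 lymphocyte markers fell (3), with the immunoglobulin gene Ighm at -1.22 ± 0.30 (camera adjusted p = 0.00895, and 0.0753 with an estimated correlation). The lymphocyte call also ended without a filter on low counts (adjusted p = 0.141).

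Camera did not call the other lists. Adhesion and matrix genes had 12 higher and 8 lower of 30 (12 and 8, adjusted p = 0.428), with the adhesion receptor Icam1 at 1.59 ± 0.19 and the protease inhibitor Timp2 at -1.74 ± 0.14. Antigen presentation had 5 higher and 2 lower of 26 (5 and 2, adjusted p = 0.569), with Cd274, which encodes PD-L1, at 1.46 ± 0.14. Of 42 interferon-stimulated genes 6 were higher (5, adjusted p = 0.155), among them Ifi205 (2.53 ± 0.47). Lipid genes had 6 higher and 9 lower of 39 (6 and 11, adjusted p = 0.428), with the sterol hydroxylase Cyp27a1 at -1.90 ± 0.16. Their median was -0.16 and their mean 0.015. Stress-response genes had 4 higher of 35 (3, adjusted p = 0.2), among them the phosphatase subunit Ppp1r15a (1.22 ± 0.21). Osteoclast markers had 2 higher and 1 lower of 10 (2 and 1, adjusted p = 0.915), with Tcirg1 at 0.09 ± 0.18. Dendritic cell markers had 1 and 1 of 5 (1 and 1, adjusted p = 0.937), with Bst2 at 0.06 ± 0.15. Stromal markers had 1 higher of 4 (1, adjusted p = 0.906), with Fabp4 at -0.16 ± 0.26. In the model with the replicate block interferon-stimulated genes had 11 higher and 4 lower, lipid genes 8 and 14, stress-response genes 7 and 2, antigen presentation 6 and 4, osteoclast markers 2 and 3 and stromal markers 1 and 1. Among the called lists it gave 4 higher and 16 lower lysosome genes, 5 and 15 macrophage identity genes, 24 and 3 glycolysis genes and 16 and 5 apoptosis genes.

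Erythroid and megakaryocyte markers had 1 higher and 1 lower of 3 (1 and 1, adjusted p = 0.969), with Pf4 at 0.16 ± 0.20 and a positive median of 0.16 against a test direction downwards. Of 40 oxidative phosphorylation genes Cox5a rose (0.30 ± 0.10, adjusted p = 0.043), none did adjusted over the list alone, and the list had adjusted p = 0.82. The call of Cox5a ended on leaving out any library except TNFα 3 and DMSO 4 (highest adjusted p = 0.146, without DMSO 3), without a filter (adjusted p = 0.118) and with unstranded counts (adjusted p = 0.179). By edgeR 0 of 25 other HDACs and corepressors were called (2 at an unadjusted p under 0.05, 0 by DESeq2, 3 by limma with weights, list adjusted p = 0.845). The same counts for 40 ribosomal protein genes were 0, 2, 1 and 4 (adjusted p = 0.179), with Rplp0 at 0.16 ± 0.13. They were 0 throughout for 9 mitochondrial transcripts (adjusted p = 0.87), with mt-Co1 at 0.01 ± 0.21, and for the mast cell marker Il3ra (-0.18 ± 0.33, list adjusted p = 0.906). The replicate block gave 1 lower HDAC or corepressor gene and 1 higher and 1 lower ribosomal protein gene.

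**Figure D2:**
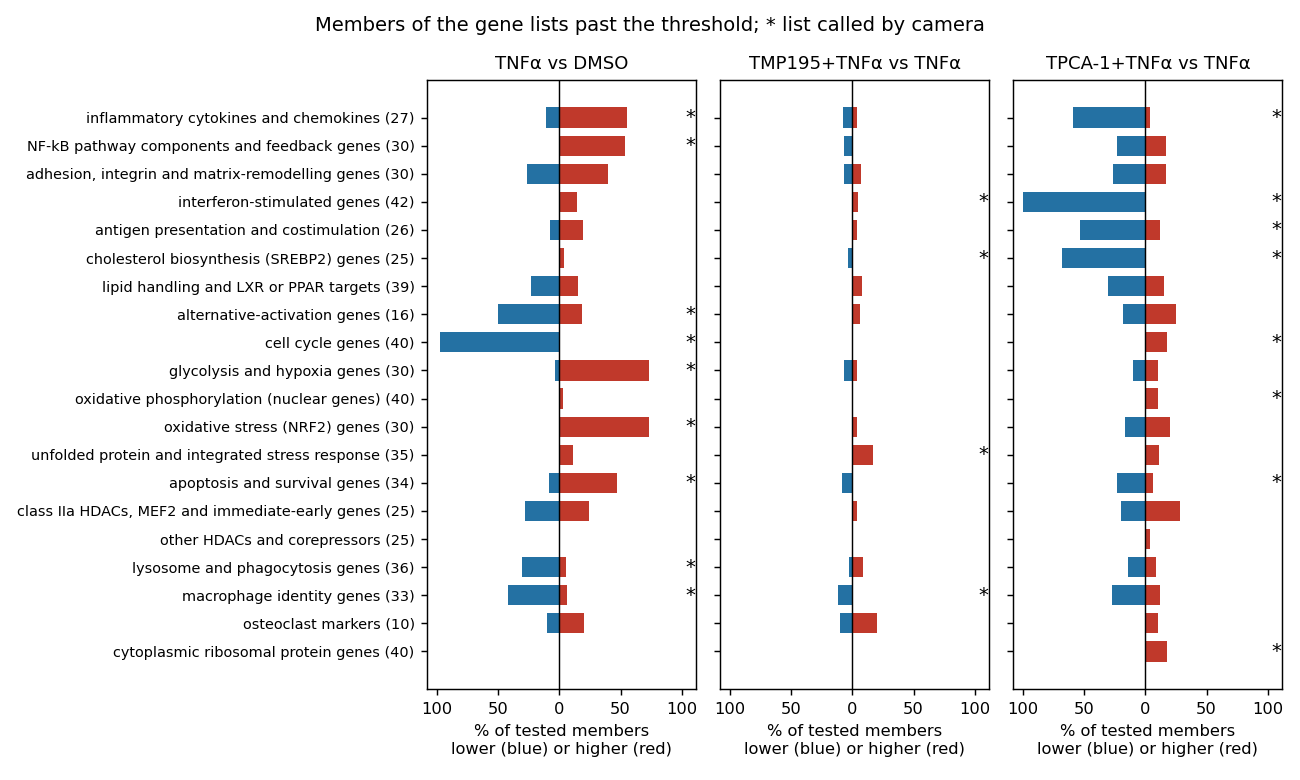
Percentage of the tested members of each gene list that were higher (red) or lower (blue) in 3 contrasts, for lists with at least 10 tested members; an asterisk marks a list called by camera. With TPCA-1, 42 of 42 interferon-stimulated genes were lower than with TNFα alone, and with TNFα 39 of 40 cell cycle genes were lower than in DMSO.

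The second comparison asks how TMP195 changed cells stimulated with TNFα. With TMP195, the cell cycle inhibitor gene Cdkn1c (ENSMUSG00000037664, chromosome 7, 143458339 to 143461050) stood at 34.3 ± 3.31 CPM against 4.79 ± 1.34 CPM with TNFα alone (log2 2.84 ± 0.33, adjusted p = 0.000137). The angiogenic factor Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369) stood at 28.2 ± 2.37 against 10.4 ± 1.01 CPM (1.44 ± 0.13, adjusted p = 3.34e-05). Ptgs2 fell from 116 ± 21.02 to 52.5 ± 10.9 CPM (-1.15 ± 0.23, adjusted p = 0.00673). Of 35 genes of the unfolded protein and integrated stress response 6 rose, and of 25 cholesterol synthesis genes 1 fell. Camera called both lists, but not with an estimated correlation (adjusted p = 0.527 for each) or by fry (adjusted p = 0.105 and 0.166). In all, 372 genes were higher and 378 lower, 206 of these 750 by at least 2-fold. Leaving out TNFα 1, TNFα 4 or TMP195+TNFα 3 left 496, 485 and 446 changed genes. With the replicate number as a block 1699 genes changed, 750 of them shared with the model without a block.

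Within the same filters the other rising genes with the largest changes were the pseudokinase Trib3 (2.16 ± 0.48), the inhibitory ligand Cd200 (1.98 ± 0.40), the protease inhibitor Serpinb9b (1.83 ± 0.37), podoplanin Pdpn (1.58 ± 0.31) and Tmem154 (1.57 ± 0.27). The falling ones were Shisa3 (-1.59 ± 0.35), the procollagen protease Bmp1 (-1.51 ± 0.21), the receptor Gpr18 (-1.50 ± 0.18), the gap junction gene Gja1 (-1.46 ± 0.22), Gtse1 (-1.43 ± 0.33) and Plppr4 (-1.41 ± 0.37). These 11 genes had adjusted p values from 0.000251 to 0.0305. The call of Plppr4 ended without TNFα 2 (adjusted p = 0.106, the highest), or without TMP195+TNFα 1, 3 or 4. Shisa3, Bmp1, Gja1 and Plppr4 had risen with TNFα, by 3.97 ± 0.41, 3.45 ± 0.24, 2.42 ± 0.24 and 2.85 ± 0.41. Gtse1 had not passed the test there (-0.07 ± 0.31, adjusted p = 0.91).

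Unfolded protein and integrated stress response genes rose in 6 of 35 cases (11, with 1 lower), including Trib3, the asparagine synthetase Asns (1.07 ± 0.24) and the folate enzyme Mthfd2 (0.80 ± 0.19). The stress-response list had a camera adjusted p = 0.0013, and 0.527 with an estimated correlation and 0.105 by fry. The call of Mthfd2 ended without TNFα 1 (adjusted p = 0.0705, the highest), TNFα 3 or TMP195+TNFα 4. The cholesterol biosynthesis list was lower, with a median of -0.76 over 25 genes, although only the sterol transporter Stard4 fell over all genes (-1.15 ± 0.33, adjusted p = 0.0441) and 12 adjusted over the list alone. The cholesterol list had a camera adjusted p = 3.51e-07, and 0.527 with an estimated correlation and 0.166 by fry. Leaving out any library except TNFα 2 and TMP195+TNFα 4 ended the call of Stard4 (highest adjusted p = 0.131, without TNFα 4). With the replicate block 14 stress-response genes rose and 2 fell, and 15 cholesterol genes fell.

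Interferon-stimulated genes were higher in 2 of 42 cases (2), the antiviral genes Rsad2 (1.38 ± 0.38) and Oasl1 (1.04 ± 0.23), and in 11 with the replicate block. The interferon-stimulated list had a camera adjusted p = 0.0145, and 0.666 with an estimated correlation and 0.421 by fry. That call ended without TMP195+TNFα 1 (adjusted p = 0.64), TNFα 2 (adjusted p = 0.0868) or TNFα 4 (adjusted p = 0.064). Rsad2 lost its call on leaving out any library except TMP195+TNFα 4 (highest adjusted p = 0.151, without TMP195+TNFα 1). Macrophage identity genes fell in 4 of 33 cases (9, with 1 higher), among them the marker Aif1 (-0.72 ± 0.16), Adgre1, which encodes F4/80 (-0.62 ± 0.14), and the Fc receptor chain Fcer1g (-0.46 ± 0.10). The macrophage identity list had a camera adjusted p = 0.0246, and 0.527 with an estimated correlation and 0.139 by fry. This call ended without TMP195+TNFα 2 (adjusted p = 0.0893), TNFα 3 (adjusted p = 0.0645) or TNFα 4 (adjusted p = 0.064), and that of Adgre1 without TMP195+TNFα 2 (adjusted p = 0.0558). Neutrophil markers were lower as a list (camera adjusted p = 0.0136, and 0.462 with an estimated correlation). Of their 4 members 1 fell (3), Lcn2 (-0.94 ± 0.25, adjusted p = 0.0334, chosen after its value was seen), and Csf3r stood at -0.23 ± 0.23 (adjusted p = 0.702). The call of Lcn2 ended without TNFα 1, 3 or 4 or TMP195+TNFα 1, 2 or 3 (highest adjusted p = 0.108, without TMP195+TNFα 2). With the replicate block 9 macrophage identity genes fell and 2 rose, and 3 neutrophil markers fell.

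The inflammatory lists were not called. Of 27 cytokines and chemokines 1 was higher and 2 lower (2 and 2, adjusted p = 0.0634). Besides Ptgs2 these were the growth factor Csf1 (1.23 ± 0.26) and the chemokine Ccl3 (-0.36 ± 0.10), named after their values were seen. Of 30 NF-kB genes 2 fell (2, adjusted p = 0.0634), the cofactor Nfkbiz (-0.70 ± 0.14, adjusted p = 0.00716) and the kinase Map3k8 (-0.46 ± 0.11, chosen after its value was seen). Leaving out any 1 library ended the call of Ccl3 (highest adjusted p = 0.105, without TNFα 2), and so did the lack of a filter (adjusted p = 0.101). That of Map3k8 ended without TNFα 1 or 2 or TMP195+TNFα 3 or 4 (highest adjusted p = 0.0697, without TMP195+TNFα 4). Tnf (-0.26 ± 0.16, adjusted p = 0.435), Nfkbia (-0.31 ± 0.19, adjusted p = 0.459) and Il6 (-0.74 ± 0.41, adjusted p = 0.365) did not pass. Nor did Il1b (-1.09 ± 0.38, adjusted p = 0.105), Ccl2 (-0.75 ± 0.34, adjusted p = 0.247) or Icam1 (-0.55 ± 0.19, adjusted p = 0.096). With the replicate block Il1b (-1.10 ± 0.30, adjusted p = 0.0225), Ccl2 (-0.82 ± 0.19, adjusted p = 0.0098) and Icam1 (-0.54 ± 0.13, adjusted p = 0.00953) fell. In that model 8 cytokines and 5 NF-kB genes were lower and 3 and 1 higher.

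Hdac9 stood at -0.51 ± 0.19 (adjusted p = 0.134), and at -0.51 ± 0.16 (adjusted p = 0.0472) with the block. Hdac4 (-0.08 ± 0.16, adjusted p = 0.888), Hdac5 (-0.12 ± 0.20, adjusted p = 0.858) and Hdac7 (0.14 ± 0.21, adjusted p = 0.835) did not pass. Neither did Ikbkb (-0.04 ± 0.08, adjusted p = 0.891) or Chuk (-0.05 ± 0.15, adjusted p = 0.931). The list of class IIa HDACs, MEF2 and immediate-early genes had 1 of 25 higher (1, adjusted p = 0.986), with a median of -0.06 and a mean of 0.052. This was the phosphatase Dusp4 (0.72 ± 0.17, adjusted p = 0.015), whose call ended without TNFα 1 (adjusted p = 0.0565). With the block 2 members of this list were higher and 3 lower.

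Adhesion genes had 2 higher and 2 lower of 30 (3 and 6, adjusted p = 0.0634), with the integrin Itgal at -1.11 ± 0.18. Lysosome genes had 3 and 1 of 36 (6 and 3, adjusted p = 0.144), with the protease Ctsc at -1.01 ± 0.19. Lipid genes had 3 higher of 39 (9 and 6, adjusted p = 0.466), among them the galectin Lgals3 (1.04 ± 0.17) and the fatty acid binding protein Fabp4 (1.23 ± 0.26). The lipid median was -0.02 with a test direction upwards. Apoptosis genes had 3 lower of 34 (1 and 5, adjusted p = 0.0634), with the survival gene Bcl2a1d at -0.73 ± 0.18. The replicate block gave 7 lower and 1 higher (adjusted p = 0.045, and 0.511 with an estimated correlation). Antigen presentation had 1 higher of 26 (1, adjusted p = 0.0634), H2-Q4 (0.72 ± 0.18). Alternative activation had Vegfa higher of 16 (2, adjusted p = 0.201), and NRF2 genes had the autophagy receptor Sqstm1 (0.77 ± 0.22) higher of 30, none adjusted over the list alone (list adjusted p = 0.0656). Glycolysis genes had 1 higher and 2 lower of 30 (1 and 2, adjusted p = 0.364), with the phosphofructokinase Pfkp at 0.57 ± 0.14. In the model with the block, which called only apoptosis among these, lipid genes had 11 higher and 8 lower, adhesion genes 4 and 7, lysosome genes 7 and 3, and antigen presentation and NRF2 genes 5 and 0 each. Alternative activation had 3 and 1 there and glycolysis genes 2 and 3.

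Single libraries ended 4 of these calls. For Bcl2a1d they were TNFα 3 or 4 and TMP195+TNFα 1 or 3 (highest adjusted p = 0.0697, without TMP195+TNFα 1). For H2-Q4 they were TNFα 1 or 4 and TMP195+TNFα 2, 3 or 4 (highest adjusted p = 0.0883, without TNFα 1). For Sqstm1 any library except TMP195+TNFα 1 did so (highest adjusted p = 0.135, without TMP195+TNFα 4). For Pfkp they were TNFα 1 or 2 and TMP195+TNFα 3 or 4 (highest adjusted p = 0.082, without TNFα 1). Osteoclast markers had 2 higher and 1 lower of 10 (4 and 1, adjusted p = 0.291), with Tcirg1 at 0.20 ± 0.18. Dendritic cell markers had 1 and 1 of 5 (1 and 1, adjusted p = 0.988), with Bst2 at 0.04 ± 0.15 and a median of 0.04 against a test direction downwards. Stromal markers had 2 higher of 4 (2 and 1, adjusted p = 0.303), with Fabp4 as above. Lymphocyte markers had 1 lower of 3 (1 and 2, adjusted p = 0.317), which was Ighm (-1.11 ± 0.30, adjusted p = 0.0387). The call of Ighm ended on leaving out any library except TNFα 1 and TNFα 2 (highest adjusted p = 0.142, without TNFα 4), and the replicate block gave 2 lower lymphocyte markers.

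By edgeR 0 of 40 cell cycle genes were called (3 at an unadjusted p under 0.05, 0 by DESeq2, 1 by limma with weights, list adjusted p = 0.0634). The replicate block gave 2 higher (list adjusted p = 0.0463, and 0.668 with an estimated correlation). The same 4 counts were 0, 2, 0 and 1 for 40 oxidative phosphorylation genes (adjusted p = 0.144) and 0, 3, 2 and 3 for 25 other HDACs and corepressors (adjusted p = 0.523), and the block gave 2 lower genes in each of these 2 lists. They were 0 throughout for 3 erythroid markers (Pf4 0.14 ± 0.20, list adjusted p = 0.932, median 0.14 against a test direction downwards) and the mast cell marker Il3ra (0.30 ± 0.33, list adjusted p = 0.648). They were also 0 for 9 mitochondrial transcripts (mt-Co1 -0.12 ± 0.21, list adjusted p = 0.201) and 40 ribosomal protein genes (Rplp0 -0.20 ± 0.13, list adjusted p = 0.0634).

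The third comparison asks how TPCA-1 changed cells stimulated with TNFα. Interferon-stimulated genes, the antiviral set that type I interferon switches on, fell in 42 of 42 cases (list adjusted p = 0.0559 with an estimated correlation). Oasl2 (ENSMUSG00000029561, chromosome 5, 114896936 to 114912234), of the oligoadenylate synthetase family, went from 320 ± 45.5 CPM with TNFα alone to 5.75 ± 1.37 CPM, and Oas3 from 177 ± 12.1 to 3.83 ± 0.706 CPM. Tnf fell from 594 ± 95.9 to 226 ± 50.2 CPM and Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) from 15.3 ± 4.77 to 2.10 ± 1.53 CPM. Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), which recruits monocytes, fell from 73.7 ± 24.3 to 13.2 ± 5.18 CPM. In all, 1220 genes were higher and 1226 lower, 902 of these 2446 by at least 2-fold. Without TPCA-1+TNFα 2 there were 1952, of which 1807 were shared. With the 8 libraries of these groups alone in the model 1551 changed.

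**Figure D3:**
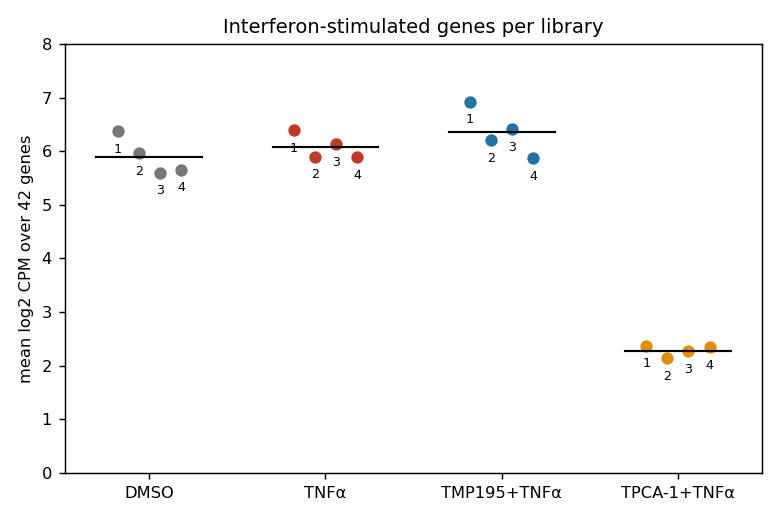
Mean log2 CPM of the 42 interferon-stimulated genes in each of the 16 libraries, by group. The TPCA-1+TNFα libraries lie at 2.14 to 2.37 and the 12 others at 5.60 to 6.92.

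Within the filters for named genes the largest falls were in Ifi208, described below, and in Ifi213 (-7.00 ± 0.67), Ifi44 (-6.05 ± 0.60), Ifit3b (-5.84 ± 0.55), Oasl2 (-5.78 ± 0.20, adjusted p = 5.51e-12) and the nucleic acid sensor Zbp1 (-5.67 ± 0.34). Ifi208 had 449 reads in the TNFα libraries and 1 in the TPCA-1+TNFα libraries, a ratio of 346 (exact 95% counting interval 61.7 to 13680). Its fitted change of -8.05 ± 2.40 (adjusted p = 0.0259) depends on the prior count. The call of Ifi208 ended without TNFα 1 or any 1 TPCA-1+TNFα library (highest adjusted p = 0.0784, without TPCA-1+TNFα 4). The median of the interferon-stimulated list was -3.86 (42 lower adjusted over the list alone, and 42 without TPCA-1+TNFα 2), and Oas3 (-5.55 ± 0.19) and Oas1a (-3.11 ± 0.12) were also among its clearest members. The interferon-stimulated list had a camera adjusted p = 7.57e-58, and 0.0559 with an estimated correlation. Antigen presentation genes fell in 14 of 26 cases and rose in 3 (16 and 3), or in 17 and 2 of 27 without TPCA-1+TNFα 2. Lower members were H2-T23 (-2.24 ± 0.14), Nlrc5, the activator of class I genes (-1.88 ± 0.16), and the proteasome regulator Psme1 (-0.79 ± 0.09). Camera gave antigen presentation an adjusted p = 1.65e-08, and 0.0559 with an estimated correlation. The 3 that rose, named after their values were seen, were Cd86 (0.88 ± 0.21), Cd74 (0.78 ± 0.25) and Ifi30 (0.74 ± 0.12), which serve costimulation and the class II pathway. The call of Cd74 ended on leaving out any library except TPCA-1+TNFα 1 and 3 (highest adjusted p = 0.128, without TPCA-1+TNFα 2), and by limma with weights (adjusted p = 0.0757).

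Cytokines and chemokines fell in 16 of 27 cases and rose in 1 (20 and 1), or in 17 and 1 of 28 without TPCA-1+TNFα 2. Camera gave this list an adjusted p = 1.28e-08, and 0.0559 with an estimated correlation. Il1a (-2.89 ± 0.34), Il1b (-2.86 ± 0.43, adjusted p = 0.000142), Ccl2 (-2.45 ± 0.37, adjusted p = 0.000146), Il18 (-1.61 ± 0.22) and Tnf (-1.39 ± 0.16, adjusted p = 1.21e-05) fell. The T-cell chemoattractant Ccl5 rose (1.64 ± 0.41, adjusted p = 0.00955, chosen after its value was seen), a call that ended without TPCA-1+TNFα 4 (adjusted p = 0.0542). Il6 (0.75 ± 0.38, adjusted p = 0.176), Icam1 (-0.08 ± 0.19, adjusted p = 0.784) and Nfkbia (-0.47 ± 0.20, adjusted p = 0.105) did not pass. NF-kB pathway and feedback genes went both ways, with 5 higher and 7 lower of 30 (6 and 7, adjusted p = 0.741, median 0.015, mean -0.038). The deubiquitinase gene Tnfaip3, which restrains NF-kB, fell (-1.13 ± 0.13, adjusted p = 7.29e-06). Map3k14, the kinase of the non-canonical pathway, rose (1.29 ± 0.25, adjusted p = 0.0014, chosen after its value was seen). Chuk fell by 0.44 ± 0.15 (adjusted p = 0.0424), a call lost on leaving out any library except TNFα 4 and TPCA-1+TNFα 1 (highest adjusted p = 0.13, without TNFα 2). Ikbkb stood at -0.12 ± 0.08 (adjusted p = 0.337). Hdac9 (-0.16 ± 0.19, adjusted p = 0.587), Hdac4 (0.06 ± 0.16, adjusted p = 0.813), Hdac5 (0.44 ± 0.20, adjusted p = 0.13) and Hdac7 (-0.45 ± 0.22, adjusted p = 0.164) did not pass. With the replicate number as a block Il6 (0.67 ± 0.24, adjusted p = 0.0428), Nfkbia (-0.46 ± 0.16, adjusted p = 0.0382), Hdac5 (0.45 ± 0.15, adjusted p = 0.0293) and Hdac7 (-0.45 ± 0.14, adjusted p = 0.0258) passed. With the block and without TPCA-1+TNFα 2, 3 of these did, Il6 (0.71 ± 0.24, adjusted p = 0.0308), Nfkbia (-0.70 ± 0.10, adjusted p = 7.51e-05) and Hdac7 (-0.48 ± 0.15, adjusted p = 0.0203).

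Cholesterol biosynthesis genes fell in 17 of 25 cases (17), and in 16 without TPCA-1+TNFα 2, with a median of -1.30. Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), a synthase early in the pathway, went from 43.2 ± 14.1 to 14.6 ± 3.18 CPM (-1.55 ± 0.29). Hsd17b7 (-1.84 ± 0.28), another enzyme of the pathway, fell too. The cholesterol list had a camera adjusted p = 1.62e-07, and 0.556 with an estimated correlation. Cell cycle genes rose in 7 of 40 (6), and in 6 without TPCA-1+TNFα 2, including Mcm5 (0.98 ± 0.20), the thymidylate synthase Tyms (0.89 ± 0.17) and Mcm7 (0.72 ± 0.19). The cell cycle list had a camera adjusted p = 0.00164, and 0.743 with an estimated correlation and 0.133 by fry. The call of Mcm7 ended without TNFα 3 (adjusted p = 0.0528).

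Apoptosis genes fell in 8 of 34 and rose in 2 (10 and 3), or in 8 and 1 without TPCA-1+TNFα 2. Casp4, the inflammatory caspase (-1.52 ± 0.17), and Ier3 (-1.32 ± 0.14) were lower and the pro-apoptotic Bcl2l11 higher (0.87 ± 0.10). The apoptosis list had a camera adjusted p = 0.0386, and 0.207 with an estimated correlation. That call ended without TPCA-1+TNFα 2 (adjusted p = 0.0816), TPCA-1+TNFα 3 (adjusted p = 0.0621) or TNFα 4 (adjusted p = 0.072). Neutrophil markers fell in 3 of 4 (3), and in 3 without TPCA-1+TNFα 2, among them Csf3r (-1.19 ± 0.24). Camera gave neutrophil markers an adjusted p = 0.00305, and 0.0836 with an estimated correlation and 0.0652 without a filter.

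Ribosomal protein genes rose in 7 of 40 (8), with Rplp0 at 0.40 ± 0.13 (adjusted p = 0.042). Camera gave an adjusted p = 0.000577, and 0.207 with an estimated correlation. These genes took 5.34% of the counts in TPCA-1+TNFα 2 and 3.71% to 4.66% elsewhere. Without that library edgeR called 0 of 40 (9 at an unadjusted p under 0.05). With the block as well, 13 rose (camera adjusted p = 0.000286, and 0.434 with an estimated correlation). Oxidative phosphorylation genes rose in 4 of 40 (0), and in 1 without TPCA-1+TNFα 2. This list had a camera adjusted p = 0.0451, and 0.725 with an estimated correlation, 0.0789 by fry and 0.203 without a filter. Its call ended without TPCA-1+TNFα 2 (adjusted p = 0.245), TNFα 1 (adjusted p = 0.0506), TNFα 2 (adjusted p = 0.0856) or TNFα 4 (adjusted p = 0.072). Cyc1 (0.54 ± 0.18, adjusted p = 0.0411) and Cox5a (0.38 ± 0.10, adjusted p = 0.0139), of the respiratory chain, and Atp5b (0.38 ± 0.13, adjusted p = 0.0447), of ATP synthase, rose. For Cyc1 and Atp5b the call ended without TNFα 1, 2 or 3 or TPCA-1+TNFα 2 or 4 (highest adjusted p = 0.17, without TPCA-1+TNFα 2, and 0.19, without TPCA-1+TNFα 4). That of Cox5a ended without TNFα 3 (adjusted p = 0.0579). Rplp0 lost its call on leaving out any library except TNFα 4 and TPCA-1+TNFα 1 (highest adjusted p = 0.144, without TNFα 1). Without a filter the calls of Cox5a (adjusted p = 0.0665), Atp5b (adjusted p = 0.101) and Rplp0 (adjusted p = 0.0854) ended as well.

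Within the filters for named genes the largest rises were in Kctd12b (3.42 ± 0.27), the transcription factor Spib (3.11 ± 0.38, from 4.38 ± 1.86 to 38.2 ± 15.8 CPM), the small nuclear RNA Rn7sk (3.11 ± 0.28) and Lad1 (2.94 ± 0.69). The dendritic cell activation marker Cd83 (2.63 ± 0.29) and the kinase Srpk3 (2.604 ± 0.447) followed, and these 6 genes had adjusted p values from 1.53e-07 to 0.00594. Lad1 stood at 63.2 CPM in TPCA-1+TNFα 2 and 11.4 to 16.1 CPM in the rest of its group. The remaining lists were not called. Macrophage identity genes had 4 higher and 9 lower of 33 (4 and 9, adjusted p = 0.27), with the Fc receptor Fcgr1 at -2.44 ± 0.24. Lipid genes had 6 and 12 of 39 (7 and 12, adjusted p = 0.434), with the nuclear receptor Pparg at 1.22 ± 0.13. Adhesion genes had 5 and 8 of 30 (7 and 9, adjusted p = 0.324), with the matrix protease Mmp14 at -2.33 ± 0.25. NRF2 genes had 6 and 5 of 30 (7 and 5, adjusted p = 0.737), with Sod2 at -1.74 ± 0.18. The HDAC and MEF2 list had 7 and 5 of 25 (8 and 5, adjusted p = 0.382), or 6 and 2 without TPCA-1+TNFα 2, with the phosphatase Dusp6 at -1.79 ± 0.19. Alternative activation had 4 and 3 of 16 (4 and 3, adjusted p = 0.896), with Vegfa at 0.75 ± 0.13. Glycolysis had 3 and 3 of 30 (3 and 3, adjusted p = 0.962), with the hexokinase Hk2 at -0.58 ± 0.13. Lysosome genes had 3 and 5 of 36 (7 and 6, adjusted p = 0.529), with the transcription factor Mitf at -0.86 ± 0.11.

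Stress-response genes had 4 higher of 35 (2, adjusted p = 0.434), among them the transcription factor Atf3 (1.17 ± 0.19). Osteoclast markers had 1 higher of 10 (1, adjusted p = 0.465), with Tcirg1 at 0.49 ± 0.18. Lymphocyte markers had 2 higher of 3 (2, adjusted p = 0.0519), and 1 without TPCA-1+TNFα 2, with Ighm at 0.94 ± 0.30. Dendritic cell markers had 3 and 1 of 5 (3 and 1, adjusted p = 0.636), with Bst2 at -1.94 ± 0.16. Erythroid and megakaryocyte markers had 1 and 2 of 3 (1 and 2, adjusted p = 0.434), with the platelet chemokine Pf4 at -0.95 ± 0.20. Stromal markers had 1 and 1 of 4 (1 and 1, adjusted p = 0.92, median -0.16, mean 0.16), with Fabp4 at -1.11 ± 0.27. Of 25 other HDACs and corepressors the deacetylase Sirt7 rose (0.58 ± 0.17), none did adjusted over the list alone, and the list had adjusted p = 0.8. The calls of Ighm and Sirt7 ended without TNFα 1, 2 or 3 or TPCA-1+TNFα 2 or 4 (highest adjusted p = 0.168, without TPCA-1+TNFα 4, and 0.105, without TPCA-1+TNFα 2). By edgeR 0 of 9 mitochondrial transcripts were called (0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma with weights), with mt-Co1 at -0.13 ± 0.21 (list adjusted p = 0.434). These counts were also 0 for the mast cell marker Il3ra (0.35 ± 0.34, list adjusted p = 0.8).

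**Figure D4:**
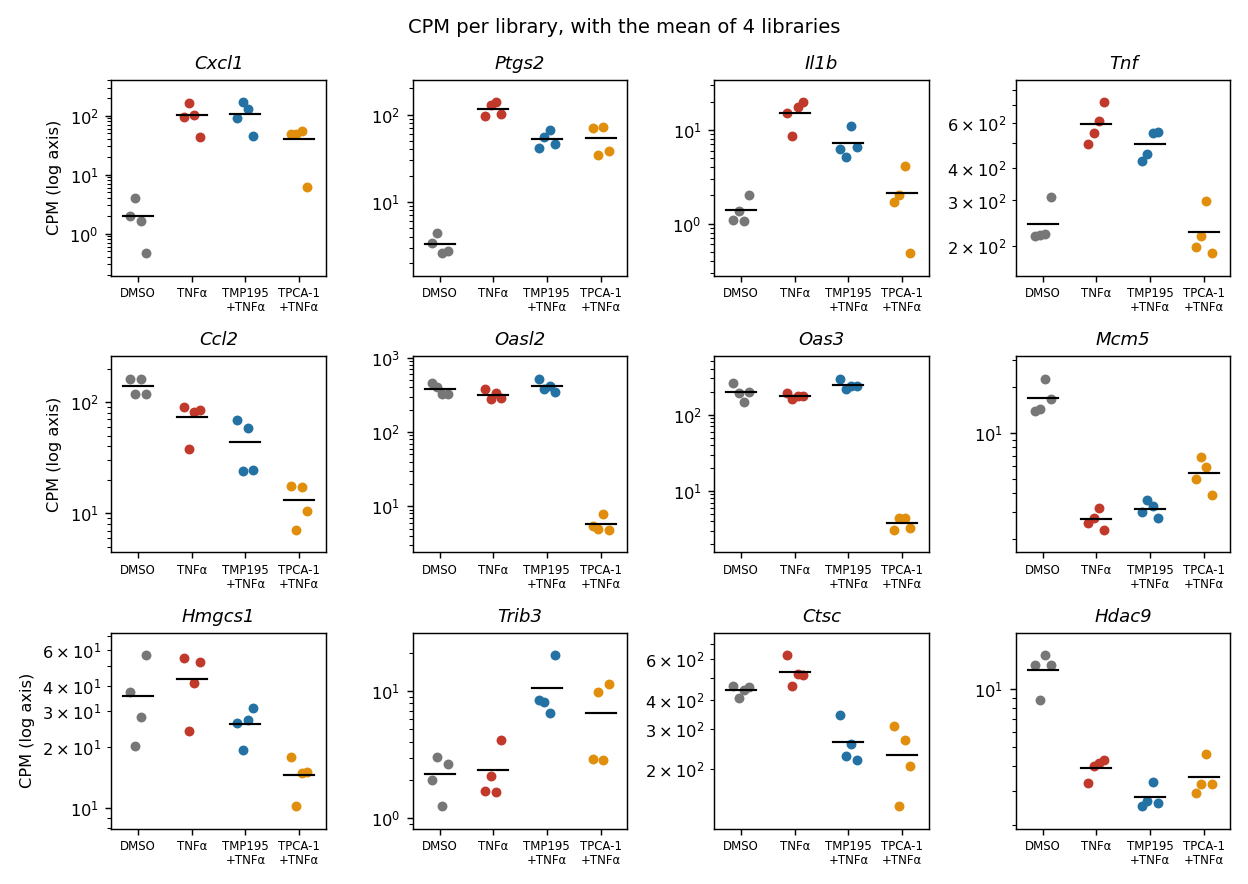
CPM of 12 genes in each library, on a log axis; points are libraries and lines the mean of the 4 libraries of a group. Oasl2 lies at a mean of 5.75 CPM with TPCA-1 and 320 CPM with TNFα alone, and Ptgs2 at 52.5 CPM with TMP195 and 116 CPM with TNFα alone.

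The direct comparison asks where the inhibitors differ in stimulated cells. Interferon-stimulated genes were higher with TMP195 than with TPCA-1 in 42 of 42 cases (42), with a median of 4.28. Within the filters for named genes the largest differences were in Ifi208 (fitted at 8.85 ± 2.29, adjusted p = 0.00864, resting on its 1 read in the TPCA-1+TNFα libraries), Ifi213 (7.66 ± 0.66), Ifi44 (6.54 ± 0.61) and Ifi206 (6.32 ± 0.53). The interferon-stimulated list had a camera adjusted p = 2.74e-50, and 0.0456 with an estimated correlation. Antigen presentation genes were higher in 17 of 26 and lower in 2 (19 and 2). Camera gave antigen presentation an adjusted p = 3.34e-09, and 0.0456 with an estimated correlation. Both of these calls ended with an estimated correlation and the replicate block together (adjusted p = 0.079 for each). Cytokines were higher in 16 of 27 and lower in 4 (19 and 5), with Tnf at 1.13 ± 0.16 (adjusted p = 7.57e-05), Il1b at 1.77 ± 0.43 (adjusted p = 0.00537) and Ccl2 at 1.70 ± 0.36 (adjusted p = 0.00219). The cytokine list had a camera adjusted p = 0.000123, and 0.248 with an estimated correlation. Ptgs2, lower with each inhibitor than with TNFα alone, did not differ past the threshold (-0.04 ± 0.23, adjusted p = 0.919).

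Genes lower with TMP195 than with TPCA-1 included Spib (-3.79 ± 0.40), Lad1 (-3.55 ± 0.72), the lectin Cd209g (-3.38 ± 0.69) and the microtubule gene Map1a (-3.29 ± 0.51). Cdkn1c was higher with TMP195 (2.11 ± 0.32, adjusted p = 0.000125). Ribosomal protein genes were lower in 16 of 40 cases and higher in 1 (21 and 1), and lower in 11 without TPCA-1+TNFα 2. The ribosomal list had a camera adjusted p = 1.2e-05, and 0.182 with an estimated correlation. Oxidative phosphorylation genes were lower in 9 of 40 (8), and in 4 without TPCA-1+TNFα 2. Camera gave oxidative phosphorylation an adjusted p = 0.00533, and 0.543 with an estimated correlation. The other 22 lists had adjusted p values from 0.0944 to 0.967, the cholesterol list among them with 5 of 25 higher (3, adjusted p = 0.229). In all, 1652 genes were higher and 1595 lower with TMP195, 1059 of these 3247 by at least 2-fold, and 2868 changed without TPCA-1+TNFα 2.

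Set against DMSO, several TNFα-responsive genes stayed displaced in cells given TMP195 and TNFα. Cxcl3 (7.26 ± 0.49), Cxcl1 (5.74 ± 0.70), Il1b (2.37 ± 0.44, adjusted p = 0.000487) and Tnf (1.03 ± 0.16, adjusted p = 0.000119) were above DMSO, and Mrc1 (-3.06 ± 0.28) and Hdac9 (-2.17 ± 0.19) below it. Cell cycle genes were lower in 39 of 40 cases (39, camera adjusted p = 1.21e-26, and 0.116 with an estimated correlation). Macrophage identity genes were lower in 17 of 33 and higher in 2 (20 and 3, adjusted p = 2.78e-05, and 0.192 with an estimated correlation). Lymphocyte markers were lower in 3 of 3 (3, adjusted p = 0.00458, and 0.121 with an estimated correlation and 0.189 without a filter). NRF2 genes were higher in 23 of 30 and lower in 1 (24 and 1, adjusted p = 1.84e-16, and 0.116 with an estimated correlation). Glycolysis genes were higher in 20 of 30 and lower in 1 (21 and 1, adjusted p = 3.91e-08, and 0.198 with an estimated correlation). NF-kB genes were higher in 13 of 30 and lower in 1 (14 and 1, adjusted p = 0.000223, and 0.198 with an estimated correlation). Cytokines were higher in 16 of 27 and lower in 4 (18 and 4, adjusted p = 0.000242, and 0.198 with an estimated correlation).

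Stress-response genes were above DMSO in 15 of 35 and below it in 1 (17 and 1, adjusted p = 0.000559, and 0.255 with an estimated correlation), with Mthfd2 at 1.71 ± 0.20. Interferon-stimulated genes were higher in 10 of 42 (9, camera adjusted p = 0.00164, and 0.667 with an estimated correlation and 0.121 by fry), Rsad2 among them (1.38 ± 0.38, adjusted p = 0.0115). The list's call ended without TMP195+TNFα 1 (adjusted p = 0.0963). Cholesterol genes were lower in 2 of 25 and higher in 1 (0, adjusted p = 0.198). With the replicate block 16 interferon-stimulated genes were higher and 1 lower, 22 and 3 glycolysis genes, 17 and 1 NF-kB genes, 18 and 1 stress-response genes, and 4 and 21 macrophage identity genes. Of the cholesterol genes 10 were lower and 1 higher (camera adjusted p = 0.011, and 0.647 with an estimated correlation). The other 18 lists had adjusted p values from 0.0522 to 1. In all, 1709 genes were higher and 1754 lower, 1359 of these 3463 by at least 2-fold.

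Cells given TPCA-1 and TNFα lay below DMSO in several groups of genes and above it in others. Interferon-stimulated genes were lower than in DMSO in 42 of 42 cases (42), and in 42 without TPCA-1+TNFα 2, with a median of -3.33 and Oasl2 at -6.03 ± 0.21. The interferon-stimulated list had a camera adjusted p = 2.42e-39, and 0.101 with an estimated correlation. Ccl2 was lower than in DMSO (-3.38 ± 0.38, adjusted p = 4.03e-06), while Cxcl3 (6.43 ± 0.48), Cxcl1 (4.29 ± 0.67), Ptgs2 (4.04 ± 0.27) and Traf1 (3.77 ± 0.18) were higher. Tnf (-0.10 ± 0.16, adjusted p = 0.655) and Saa3 (0.97 ± 0.50, adjusted p = 0.156) did not pass. NF-kB genes were higher in 19 and lower in 4 of 30 (19 and 4), or in 14 and 3 without TPCA-1+TNFα 2. The NF-kB list had a camera adjusted p = 2.45e-05, and 0.13 with an estimated correlation. The 27 cytokines split into 11 higher and 9 lower (11 and 9, adjusted p = 0.487). Antigen presentation had 2 higher and 14 lower of 26 (2 and 14, adjusted p = 7.1e-05, and 0.13 with an estimated correlation). Cholesterol genes were lower in 10 of 25 (14), and in 8 without TPCA-1+TNFα 2 (adjusted p = 0.00298 with all libraries, and adjusted p = 0.642 with an estimated correlation and 0.107 by fry), a call that ended without DMSO 4 (adjusted p = 0.079).

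Cell cycle genes were lower than in DMSO in 37 of 40 (38, adjusted p = 5.53e-22, and 0.13 with an estimated correlation), with Mcm5 at -1.66 ± 0.19. Lysosome genes were lower in 17 of 36 and higher in 1 (17 and 1, adjusted p = 0.00102, and 0.13 with an estimated correlation). Macrophage identity genes were lower in 17 of 33 and higher in 2 (18 and 5, adjusted p = 7.1e-05, and 0.135 with an estimated correlation). NRF2 genes were higher in 29 of 30 (29, adjusted p = 8.09e-19, and 0.0761 with an estimated correlation), with Slc7a11 at 3.22 ± 0.25. Glycolysis genes were higher in 18 of 30 and lower in 2 (21 and 2, adjusted p = 5.37e-07, and 0.16 with an estimated correlation). Ribosomal protein genes were higher in 22 of 40 (26), and in 14 without TPCA-1+TNFα 2 (adjusted p = 2.24e-05 with all libraries, and adjusted p = 0.13 with an estimated correlation). Oxidative phosphorylation genes were higher in 6 of 40 (4), and in 5 without TPCA-1+TNFα 2 (adjusted p = 0.0355 with all libraries, and adjusted p = 0.536 with an estimated correlation and 0.0927 without a filter). This last call ended without TPCA-1+TNFα 2 (adjusted p = 0.138), DMSO 1 (adjusted p = 0.0612), DMSO 2 (adjusted p = 0.0519) or DMSO 4 (adjusted p = 0.0618). The other 16 lists had adjusted p values from 0.0503 to 0.974. In all, 1871 genes were higher and 1949 lower, 1457 of these 3820 by at least 2-fold, and 3352 changed without TPCA-1+TNFα 2.

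Of the 1377 genes raised by TNFα, TMP195 lowered 8.71% and raised 4.65%, and TPCA-1 lowered 32.7% and raised 5.81%. Ptgs2 and Saa3 are among those lowered by both, and Saa3, whose TNFα and TMP195+TNFα libraries overlap, stood at -2.03 ± 0.49 with TMP195 and -5.64 ± 0.58 with TPCA-1. Its call with TMP195 ended without TNFα 3 or 4 or TMP195+TNFα 4 (highest adjusted p = 0.0607, without TNFα 3). Of the 1568 genes lowered by TNFα, TMP195 raised 8.67% and lowered 3.44%, and TPCA-1 raised 26.1% and lowered 5.74%. Both changes use the TNFα libraries, so chance alone gives opposite deviations. Simulations with no inhibitor effect gave 0% by design and cannot gauge this. With the TNFα libraries split 2 and 2 median shares of raised genes lowered were 3.59% and 26.4%. For TMP195 the share was 14.5% with the replicate block, 5.59% without TMP195+TNFα 2 and 5.71% without TNFα 4.

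Across the 12612 genes, which are not independent replicates, the changes with TMP195 and with TPCA-1 had a correlation of 0.172. It was 0.1 without TMP195+TNFα 4, 0.0882 with the stricter filter and 0.374 without a filter. Simulations without any inhibitor effect, where only noise sets the spread, gave 0.484 on average (0.454 to 0.514). The covariance was 0.0479 against a mean of 0.0360 (0.0333 to 0.0390) in the simulations. These had no pairing by number, so the difference of 0.0119 does not measure a shared effect. With the TNFα libraries split 2 and 2 the median correlation was 0.0697 (-0.0657 to 0.175) and the median covariance 0.0216 (-0.0237 to 0.0521), so both took either sign among the 6 assignments. Genes called in both contrasts numbered 100 higher in both, against 36.0 if the calls were independent, and 108 lower in both, against 36.7. Opposite calls numbered 80, against 72.7. Simulations gave 0 in each class, again by design. With the TNFα libraries split the median counts were 20.5, 31.5 and 21, against medians of 6.22, 10.4 and 16.2 if the calls were independent. Vegfa (1.44 ± 0.13 and 0.75 ± 0.13) and Trib3 (2.16 ± 0.48 and 1.47 ± 0.48) were among the genes higher with both inhibitors. Bmp1 (-1.51 ± 0.21 and 0.77 ± 0.20) and Fabp4 (1.23 ± 0.26 and -1.11 ± 0.27) were among those that went opposite ways.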

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

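Tests chosen only after their result was seen were the split count for TMP195+TNFα with TNFα, the comparisons of splits by 2-fold changes, smallest p and pairs parted, and those on leaving out TPCA-1+TNFα 2, scaling, a mislabelled sample, other organisms or adapters, and shared TNFα libraries. The other tests here were planned before their own result was seen. The second interferon list was written after the fall of the first and before the values of its own 37 members.

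Counts of changed genes were compared with those from all 35 splits of the 8 libraries of each contrast into 4 and 4. For TNFα with DMSO 1 of 35 splits, the real one, gave as many as 2945 genes and the highest other gave 0. For TMP195+TNFα with TNFα 1 of 35 gave as many as 750, and the highest other gave 1. For TMP195+TNFα with DMSO 1 of 35 gave as many as 3463, and the highest other gave 0. The libraries of these 3 contrasts are paired by number, though, and only 8 splits part all 4 pairs as the real one does, too few for a share under 0.05. The other 7 of these gave at most 0 in each contrast. The direct comparison of the inhibitors (1 of 35, 3247 genes, highest other 2428) and TPCA-1+TNFα with DMSO (1 of 35, 3820 genes, highest other 1634) are paired by number only if TPCA-1+TNFα 2 is left out, and if paired have 8 such splits too. The other 7 gave at most 0 and 1.

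For TPCA-1+TNFα with TNFα 2 of 35 splits gave as many as 2446 genes, so this count does not exclude chance. The other split exchanges TNFα 4 with TPCA-1+TNFα 1 and gave 2966 genes, which points to a structure among the samples apart from their groups. Its smallest adjusted p was 0.0252 against 5.51e-12 for the real groups. It held 291 genes with at least a 2-fold change against 902, and 0 of the 42 interferon-stimulated genes by edgeR against 42. By 2-fold changes 1 of 35 splits was as large as the real one.

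Interferon-stimulated genes under TPCA-1 lay below their DMSO level in 42 of 42 cases. They do so without TPCA-1+TNFα 2 as well (42), which argues against that library as the cause. A scaling factor shifts all genes of a library alike, but the list's median log2 count minus that of the other tested genes was -1.65 to -1.37 in the TPCA-1+TNFα libraries and 1.92 to 2.76 in the DMSO libraries, a gap of 3.29 that argues against scaling. In a second list of 37 interferon-induced genes that shares none with the other lists, 91.9% were lower than in DMSO, with a median of -1.90, so lower interferon signalling with TPCA-1 is a candidate explanation.

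TPCA-1+TNFα 2 stood apart from the other 3 libraries of its group in counted reads (7.49 against 20.43 to 20.99 in units of 1e6, gap 0.959 of the range), unmapped reads (44.02% against 4.88% to 5.76%, 0.978) and multimapped reads (6.69% against 11.09% to 11.78%, 0.864). It also did in reads outside genes (1.70% against 3.36% to 3.47%, 0.94), counted reads as a share (46.57% against 77.84% to 78.41%, 0.982) and genes with a read (14870 against 17180 to 17490, 0.884). The other libraries thinned to its depth kept 15280 to 15497 genes, so lower depth accounts for part of the shortfall and not all of it. Its mean log2 CPM of 2.14 over the interferon-stimulated genes, beside 2.27 to 2.37 in its group and 5.60 to 6.92 without TPCA-1, argues against a sample from another group. Reads from another organism or from adapters cannot be told apart from other losses, because the sequences of the 44.02% unmapped reads are not in the count files, and no biological explanation was tested.

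Camera called the cholesterol synthesis list lower with both inhibitors than with TNFα alone, with 1 (TMP195) and 17 (TPCA-1) of 25 members past the threshold, but not with an estimated correlation (adjusted p = 0.527 and 0.556), nor for TMP195 by fry (adjusted p = 0.166). High TNFα libraries shared by both comparisons would leave the inhibitor groups at the DMSO level, and 10 of 25 members were lower than DMSO with TPCA-1, which argues against that as the whole cause there, although the medians against same-number DMSO libraries were -0.867, -0.066, -0.488 and -1.47 and the list's call against DMSO ended without DMSO 4 (adjusted p = 0.079). With TMP195, paired with DMSO by number, 10 members were lower than DMSO with the replicate block (2, and no list call, without it). The same-number medians were -0.347, -0.219, -0.22 and -0.72. The count rests on the block, so that cause stays open. Differences between the replicate numbers cannot be told apart by the medians below 0 in 8 of 8 same-number pairs (-0.926, -0.386, -0.827 and -0.873 with TMP195, -1.39, -0.389, -1.30 and -1.69 with TPCA-1). These pairs share their TNFα libraries, the list was picked for being lower, and DMSO also lay below TNFα in each number (-0.544, -0.249, -0.553 and -0.103), while an effect of each compound on sterol synthesis was not tested apart from these values.

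Chance gives a library as far from the other 3 as Dixon's 95% limit for 4 samples in about 1 in 20 groups. Of 48 groups of library measures 9 passed that limit, the 6 above among them. DMSO 4 stood apart in other-strand reads (3.65%, 0.904) and in the mitochondrial share (4.24% against 5.44% to 5.50%, 0.951), and TNFα 4 in other-strand reads (3.67%, 0.974).

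Of 536 groups of named genes' levels 34 passed the limit, against 26.8 expected by chance, and the gaps follow as shares of the group's range for the genes reported here. In DMSO 4 these were Cxcl3 (0.841), Nfkbia (0.951), Hdac7 (0.86) and Tnf (0.96, 309.6 CPM against 219.1 to 222.8). In DMSO 2 they were Plppr4 (0.848), Lad1 (0.862) and Gusb (0.874), and in DMSO 1 Fcgr1 (0.92). In TNFα 2 they were Rrm2 (0.843), Plppr4 (0.913), Ccl2 (0.841) and Nlrc5 (0.843), and in TNFα 3 Bcl2l11 (0.842). TNFα 4 stood apart in Cd200 (0.862), Gja1 (0.874) and Itgal (0.984). TMP195+TNFα 4 did in Trib3 (0.862), Cd200 (0.845), Sod2 (0.856), Il3ra (0.849) and Mthfd2 (0.863). TMP195+TNFα 2 did in Egln3 (0.94) and Dusp6 (0.944), and TMP195+TNFα 1 in Tnfaip3 (0.846). TPCA-1+TNFα 1 did in Kctd12b (0.952), Atp6v0a1 (0.912), Csf3r (0.937), Icam1 (0.869) and Ifi208 (1, by its 1 read). The last were Lad1 in TPCA-1+TNFα 2 (0.909), Dusp6 in TPCA-1+TNFα 3 (0.875) and Cxcl1 in TPCA-1+TNFα 4 (0.843, 6.08 CPM against 47.97 to 55.76).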

How the results depend on the processing

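Leaving TPCA-1+TNFα 2 out of the shared fit, the block without that library and the block with an estimated correlation were tests chosen after seeing the data; the other alternatives were planned. No called list or named gene past the threshold reversed its direction in any of them. Of the list tests that were not called 35 turned their direction in at least 1 alternative other than the block without that library (lowest adjusted p = 0.176 there), 5 of them with the replicate block, such as erythroid and osteoclast markers for TNFα with DMSO and alternative activation for TPCA-1+TNFα with TNFα. Where a value moved the cause was not tested unless fewer libraries or genes show it. Counts of changed genes stayed within 1.5 times in 92 alternatives and moved in 16. The agreement measures moved by less than their SD over the 6 split assignments (0.0986 for the correlation, 1.56 and 1.88 percentage points for the shares) in 30 and by more in 24, and counts of called lists stayed in 71 and moved in 22. Called lists kept their call in 643 and lost it in 132, among them every list but 2 with an estimated correlation and every list with the block and an estimated correlation (adjusted p = 0.079 for those 2). Of 145 named gene results 124 kept their call in each alternative run on them, which were not all those listed. A 2-fold threshold gave 1242, 206, 902, 1059, 1359 and 1457 genes in the order of the report. For TMP195+TNFα with TNFα the DESeq2 test gave 1209 genes (748 shared), limma with weights 1778 (745 shared) and the replicate block 1699 (750 shared). Leaving out single libraries gave 446 (without TMP195+TNFα 3) to 597 (without TNFα 2), where fewer libraries enter the test. For TPCA-1+TNFα with TNFα the 2 groups alone gave 1551 (1538 shared), the block 3835 and the block without TPCA-1+TNFα 2 3839. That last setting gave 4892 for the direct comparison. With the block and without that library, camera no longer called oxidative phosphorylation for TPCA-1+TNFα with TNFα (adjusted p = 0.125) and with DMSO (0.0935) or apoptosis genes with TNFα (0.078). It called lysosome (0.0369) and lymphocyte (0.0369) lists with TNFα, cholesterol (2.8e-05) and lysosome (0.00528) lists in the direct comparison, and lipid (0.0245) and stress-response (0.0095) lists with DMSO, none with an estimated correlation (0.213 to 0.605). The block with all libraries also called lymphocyte markers in the direct comparison (0.0442, and adjusted p = 0.487 with an estimated correlation), and Tcirg1 for TPCA-1+TNFα with TNFα (0.49 ± 0.16, adjusted p = 0.0329). With that library left out of the shared fit, TMP195+TNFα with TNFα had 1041 genes. The inhibitors' correlation was 0.374 without a filter, 0.0882 with the stricter filter, 0.0697 with the TNFα libraries split (-0.0657 to 0.175, among its 6 assignments) and 0.1 (without TMP195+TNFα 4) to 0.253 (without TMP195+TNFα 1) on leaving out single libraries. The share of TNFα-raised genes lowered by TMP195 was 14.5% with the block, 3.59% with the split and 5.59% (without TMP195+TNFα 2) to 10.7% (without DMSO 4) on leaving out single libraries. For TPCA-1 it was 34.6% without a filter, 36.9% with the block, 26.4% with the split and 26.2% (without TPCA-1+TNFα 4) to 37.8% (without TNFα 4). Fry, which asks for a net shift, lost the calls whose adjusted p by fry is given above. It passed other lists that camera did not call: lipid genes for TNFα with DMSO (lower, 0.0134), lymphocyte markers for TPCA-1+TNFα with TNFα (higher, 0.0016), and in the direct comparison lysosome (0.00672), lipid (0.0334) and apoptosis (0.0347) genes, higher with TMP195, and lymphocyte markers (0.000221), lower. With DMSO these were antigen presentation, alternative activation, apoptosis, lysosome, osteoclast and neutrophil lists for TMP195+TNFα (7.62e-05 to 0.026) and lipid, alternative activation, stress-response, apoptosis, osteoclast, neutrophil and erythroid lists for TPCA-1+TNFα (0.00156 to 0.04). Depth limits TPCA-1+TNFα 2 most, where 3 counts equal 0.401 CPM against at most 0.162 elsewhere.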

Other observations

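The MEF2 test was chosen after its result was seen, and so were the genes named below.

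Release of MEF2 and immediate-early genes by TMP195 was tested as a hypothesis, since class IIa HDACs hold MEF2 factors back. The list gave a camera adjusted p = 0.986 for TMP195+TNFα with TNFα, with Dusp4 as its 1 higher member of 25, and 2 higher and 3 lower members with the replicate block. This leaves the hypothesis open, because members that go both ways can hide a release of some of them.

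In a comparison of TPCA-1+TNFα with TNFα by edgeR, single noncoding RNAs are given with and without TPCA-1+TNFα 2. Rn7sk stood at 3.11 ± 0.28 (3.05 ± 0.30 without it) and Gm26917 at 2.86 ± 0.32 (adjusted p = 8.25e-06), or 2.67 ± 0.33. The mitochondrial ribosomal RNA mt-Rnr2 stood at 1.22 ± 0.24 (adjusted p = 0.00161), or 1.36 ± 0.24, and mt-Rnr1 at 1.18 ± 0.26 (adjusted p = 0.00378), or 1.37 ± 0.23. Gm42418 did not pass (-0.09 ± 0.27, adjusted p = 0.849). Protein-coding genes took 97.7% to 98.6% of counts, and whether RNA selection set these noncoding levels was not tested.

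Irf7 and Irf1, 2 members of the interferon-stimulated list, stood at -5.38 ± 0.25 (adjusted p = 2.98e-10) and -0.89 ± 0.17 (adjusted p = 0.00142) in the same comparison. Socs3, a feedback inhibitor of cytokine signalling, was 2.93 ± 0.38 higher with TNFα than in DMSO (adjusted p = 1.92e-05) and stood at -2.71 ± 0.38 with TPCA-1 against TNFα alone (adjusted p = 7.63e-05).

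The lipid list was not called with TPCA-1 (adjusted p = 0.434), and single members stood far apart. Against TNFα alone Angptl4 was at 4.14 ± 0.61 (adjusted p = 0.00012), Plin2 at 2.29 ± 0.26 (adjusted p = 8.31e-06), Fads2 at -4.47 ± 1.13 (adjusted p = 0.00992) and Scd1 at -3.87 ± 0.92 (adjusted p = 0.00685). The calls of Fads2 and Scd1 ended by limma with weights (adjusted p = 0.0918 and 0.085). Atp6v0d2, an osteoclast marker, fell with TNFα (-2.29 ± 0.32 against DMSO, adjusted p = 3.7e-05) and was higher with TMP195 than with TNFα alone (1.48 ± 0.31, adjusted p = 0.00906).

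The second list of 37 interferon-induced genes had medians of -0.04 for TNFα with DMSO, 0.08 for TMP195+TNFα with TNFα and -1.91 for TPCA-1+TNFα with TNFα. In the last contrast 36 were lower.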
